A study of Mus musculus with 10 samples.

How the data were processed

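Primary mouse microglia treated with a control gapmer (5 libraries) or with a gapmer against 3222401L13Rik (5 libraries) were profiled by total RNA sequencing with a random-primed, strand-marking library kit, per the labels' protocols. The deposited files hold whole-number read counts per gene, 1 file per library, with no normalization visible in the values, and the reads had been demultiplexed with bcl2fastq and placed on GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. Each file had 55563 entries, of which 55471 were genes and 92 were ERCC spike-in sequences. The spike-ins held 0 to 2 reads per library and were left out. Names, exon lengths and coordinates came from GENCODE M21, to which 55230 genes matched, and the 241 unmatched genes held 0.0107% of reads. Groups and replicate numbers were taken from the labels. Replicates 1 to 3 of both groups were run on lane 7 and replicates 4 and 5 on lane 8, so lanes were balanced between groups. No pair of libraries of 1 group held the same values within counting noise (chi-square per degree of freedom 1.76 to 4.48).

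Genes were filtered with filterByExpr by group, scaled with TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, group as the only term), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (limma 3.58.1), adjusted over 30 lists. The lists were homeostatic microglia, inflammatory cytokines and chemokines, NF-kB pathway, interferon response, damage-associated microglia, phagocytosis and complement, antigen presentation, Toll-like receptors and inflammasome, PU.1 target genes, myeloid transcription factors, anti-inflammatory and alternative activation, cell cycle, p53 targets, unfolded protein and integrated stress response, cholesterol and lipid, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded, lysosome, actin and migration, ribosomal proteins, and markers of astrocytes, the oligodendrocyte lineage, neurons, endothelium, fibroblasts and mural cells, border macrophages and monocytes, neutrophils, lymphocytes and erythroid cells. The design, the lists, the alternative fits other than those with background density or GC and the rule for named genes were fixed before the data were examined. The rule named 3222401L13Rik and Spi1, the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM, a proper symbol and all 5 knockdown-labelled libraries on 1 side of the control mean, up to 6 members per list with the smallest p, list genes with a library far from its group, and tested genes within 500 kb of the target. Gm44509, genes named because a count held 5 or fewer, and the genes named after background subtraction were chosen after their values were seen.

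The background measure was chosen after the data were seen. The reads of 1135 olfactory receptor genes per kilobase of exon gave each library a density, and density times exon length gave the background reads expected for each gene. These were subtracted from the counts, and genes with a background share under 5% (or under 20%) were scaled on those genes alone and tested again with the same edgeR test. The genes under 5% were also tested with that scaling and no subtraction, to tell the 2 changes apart. Other fits used DESeq2 1.42.0 (size factors and Wald test), upper-quartile scaling, library totals, no filter, a stricter filter of 5 CPM in 5 libraries, limma-voom, the replicate number as a block, lane as a covariate, each lane alone, 1 surrogate variable (sva 3.50.0), thinned counts, removal of mitochondrial, rRNA and haemoglobin genes, each library left out, an adjusted p under 0.01 and glmTreat against a 1.2-fold change. Of the 126 splits of the 10 libraries into equal groups 100 were drawn. Single measures were compared with exact two-sided permutation tests over 252 ordered splits. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

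The test was run on simulated counts with known changes in 50 genes per size. With no background difference it found 30% of genes changed 1.2-fold, 92% of those changed 1.5-fold, and 100% of those changed 2-fold or 3-fold, and called 8 of 19573 unchanged genes. With the measured background difference it called 5243 of 20118 unchanged genes, 2109 higher and 3134 lower. After background subtraction it called 9 of 3599 unchanged genes and found 75.6% of the 45 tested genes changed 1.2-fold. The runs with a background difference had a lower noise setting and changed only genes under a 5% background share. Their yields cannot be compared with those of the first run. With the lysosome list raised 1.3-fold, camera called 2 of 30 lists.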

Results

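Total RNA was sequenced from primary microglia, the resident macrophages of the brain, cultured from wild-type mice. The cells had received gapmers, short antisense oligonucleotides that direct RNase H to cut the RNA they bind. In 5 libraries the gapmer was a control, and in 5 libraries it was directed against 3222401L13Rik, a long noncoding RNA. The tables gave whole-number read counts for 55471 genes in each of the 10 libraries. In units of 1000000 reads, totals in the control libraries, replicates 1 to 5, were 5.31, 4.32, 5.21, 5.06 and 5.64. Totals in the libraries labelled knockdown were 5.59, 6.44, 6.64, 5.90 and 6.45 in the same unit. The mean total was 5.11 ± 0.489 (SD, n = 5) in the control libraries and 6.204 ± 0.439 (SD, n = 5) in the knockdown-labelled ones (exact two-sided permutation test, p = 0.0159). At least 10 reads were counted for 21717 ± 990 genes in the control libraries and for 17341 ± 983 genes in the knockdown-labelled ones (SD, n = 5 each, exact two-sided permutation test, p = 0.00794, the smallest this design allows). The labels do not say whether replicates came from separate cultures or animals, so p-values and the intervals of fold changes measure the spread between these samples, which may be technical, and the Poisson intervals drawn for 3222401L13Rik cover counting error only.

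The first comparison asked whether the targeted RNA was lower in the libraries labelled knockdown. 3222401L13Rik (ENSMUSG00000073590) was counted at 30, 29, 28, 33 and 34 reads in control replicates 1 to 5 and at 22, 38, 24, 33 and 29 reads in the knockdown-labelled replicates 1 to 5. Its mean was 30.8 ± 2.59 reads in the control and 29.2 ± 6.53 reads in the knockdown-labelled libraries (SD, n = 5 each, exact two-sided permutation test, p = 0.659). In counts per 1000000 reads (CPM, TMM-scaled) the means were 5.76 ± 0.427 and 5.11 ± 1.08 (SD, n = 5 each), and on the log2 CPM scale the exact two-sided permutation p was 0.214. The fitted log2 fold change was -0.17 (SE 0.23, 95% interval -0.63 to 0.29, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.541). The interval corresponded to 0.647 to 1.22 times the control level, so a fall larger than that lower bound lay outside it. The targeted gene therefore did not set the 2 labels apart, and every direction below is that of the libraries labelled knockdown. The gene lies on chromosome 18 at 37655451 to 37661742 (GRCm38, plus strand) and is annotated as a long intergenic noncoding RNA with 6292 bases of exon. It lies inside the span of 3 predicted protein-coding genes of the same strand (Gm42416, Gm37013 and Gm37388). Whether their exons overlap its exon was not checked, so reads shared with them are possible but not shown.

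A measure of reads from genes that microglia do not use differed between the groups, and it covered 48.0% of the reads of 3222401L13Rik. Olfactory receptor genes, which encode odorant receptors of nasal sensory neurons, were read at 0.599 ± 0.147 reads per kilobase of exon per 1000000 reads in the control libraries and at 0.257 ± 0.0674 in the knockdown-labelled ones (SD, n = 5 each, 1135 genes, exact two-sided permutation test, p = 0.00794). The control libraries were 2.33 times higher on this measure, and 2.51 times higher for 333 vomeronasal receptor genes, 2.09 times for 38 taste receptor genes and 2.22 times for 49 keratin genes. They were 2.07 times higher for 42 beta-defensin genes, and 2.85 times higher for 10 genes annotated in pericentromeric repeats. The olfactory receptors of each of 9 chromosomes showed the same direction, from 1.45 times on chromosome 17 to 2.63 times on chromosome 16. Levels were less even than ratios. In the same unit, control means were 0.385 for vomeronasal receptors, 0.656 for taste receptors, 1.02 for beta-defensins and 1.31 for keratins. For olfactory receptors they ran from 0.403 on chromosome 10 to 0.999 on chromosome 17. Background shares given here therefore depend on the class chosen. In lane 7 the means were 0.639 and 0.241 (n = 3 each), and in lane 8 they were 0.539 and 0.280 (n = 2 each). Spread evenly over the exons of all genes, this density equalled 7.83 ± 1.93% of reads in the control and 3.36 ± 0.881% in the knockdown-labelled libraries (SD, n = 5 each). For 3222401L13Rik it predicted 18.9 ± 2.79 reads per control library and 9.88 ± 1.97 reads per knockdown-labelled library (SD, n = 5 each). The reads above that prediction were 11.9 ± 4.59 and 19.3 ± 6.60 (SD, n = 5 each, exact two-sided permutation test, p = 0.0794), a log2 fold change of 0.41 (95% interval -0.35 to 1.17, edgeR quasi-likelihood test, adjusted p = 0.470). This density is called the background density in the text that follows, and the share of a gene's reads it predicts is called its background share.

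**Figure D1:**
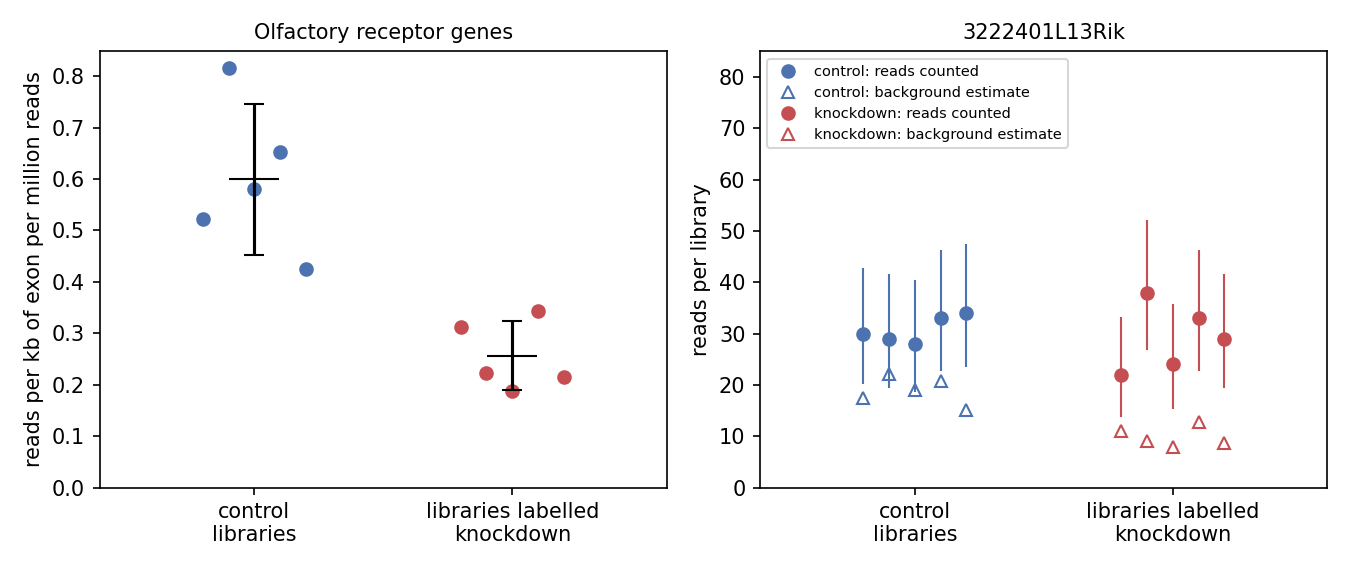
Left, reads per kilobase of olfactory receptor exon per 1000000 reads, with bars for mean and SD; right, reads of 3222401L13Rik per library (filled, with 95% Poisson intervals) and the background reads expected for it (open triangles). Points are single libraries, 5 control and 5 labelled knockdown; olfactory density averaged 0.599 and 0.257, while 3222401L13Rik averaged 30.8 and 29.2 reads.

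Of 87 genes within 500 kb of 3222401L13Rik, 49 were tested. Among them 3 rose and 26 fell, with a median log2 fold change of -0.69, and their median background share was 59.7%. All 3775 tested genes with a share of 40 to 70% had a median of -0.89, and 2683 of them fell. Falls near the target were thus not particular to its locus. Many of these neighbours overlap in span, so they are not independent. The risen genes were Taf7 (0.49, SE 0.10), a subunit of the general transcription factor TFIID, Diaph1 (0.24, SE 0.06), a formin that assembles actin filaments, and Arap3 (0.15, SE 0.06), a regulator of small GTPases. Diaph1 lost its call with upper-quartile scaling (0.09) and with library totals only (0.03), where Arap3 turned to -0.05. Arap3 also lost its call without control replicate 2 (0.13), control replicate 4 (0.14) or knockdown-labelled replicate 3 (0.16), and Arap3 was at -0.10 and Diaph1 at -0.03 after scaling on genes under a 5% background share and background subtraction, against -0.09 and -0.01 with that scaling alone. Only 2 of the tested neighbours had a background share under 5%, and neither passed the edgeR test once the expected background reads had been subtracted.

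The main comparison set the whole transcriptome of the 5 libraries labelled knockdown against that of the 5 control libraries, to ask which programs of microglia moved with the label. The largest rise among the genes named by rule was that of Mmp13, a collagenase of the extracellular matrix. Its level went from 41.5 ± 0.982 to 65.9 ± 3.30 CPM (SD, n = 5 each), a log2 fold change of 0.67 (SE 0.07, edgeR quasi-likelihood test, adjusted p = 6.2e-10), with the 2 groups of libraries not overlapping. The sodium-coupled dicarboxylate transporter gene Slc13a3 (0.64, SE 0.11), the methionine salvage enzyme gene Apip (0.64, SE 0.18), the matricellular protein gene Postn (0.63, SE 0.09), Smim13 (0.60), the Mediator subunit gene Med7 (0.60) and the C-type lectin gene Clec4a2 (0.60) followed. Trim12c (0.59), the RNA polymerase II subunit gene Polr2d (0.57), the stress response gene Gadd45a (0.55), the granzyme inhibitor gene Serpinb9 (0.55) and the apolipoprotein gene Apoc1 (0.55) closed the list of 12. Trim12c lost its call with library totals only (0.39) and with counts thinned to the smallest library (0.37). Among called genes with a mean of at least 5 CPM, a limit set by the naming rule, the 12 largest falls were those of Ranbp17 (log2 fold change -1.78, SE 0.26), the secreted metalloproteinase genes Adamts20 (-1.73, SE 0.23) and Adamts18 (-1.61, SE 0.22), the growth factor gene Fgf6 (-1.71, SE 0.27), Agbl4 (-1.62), the ephrin receptor gene Epha7 (-1.60), Spink10 (-1.58), Zdbf2 (-1.57), the calcium-sensing receptor gene Casr (-1.47), Crocc2 (-1.45), Dennd3 (-1.43) and the chloride channel gene Clic5 (-1.43). These 12 genes were low in both groups, with control means of 7.57 to 12.1 CPM, and the background density predicted 35.3 to 83.0% of their reads. For the 12 risen genes it predicted 2.04 to 14.5%.

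Of 19263 genes tested, 4418 rose and 6033 fell in the libraries labelled knockdown (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 5 against 5). Falls of more than 2-fold numbered 2889, while 1 gene, Gm44509, rose by more than that (1.16 ± 0.625 to 2.98 ± 1.34 CPM, SD, n = 5 each). The direction of a gene followed its background share. Genes with a share under 1% had a median log2 fold change of 0.28, and of these 853 genes 746 rose and 4 fell. Genes with a share over 70% had a median of -1.01, and of these 1353 genes 0 rose and 1048 fell. A share of at least 20% was seen for 93.7% of the fallen genes, and a share under 20% for 99.8% of the risen ones. Across 19248 genes, which are not independent replicates, Spearman's correlation of log2 fold change with background share was -0.83. Across the 10 libraries the first principal component of log2 CPM followed the background density (Pearson r = -0.976, Spearman r = -0.988, permutation p = 1e-05 for both, the smallest 100000 permutations give), and r was -0.986 without the 2 libraries farthest from the median density. The split of calls also moved with the scaling. Of all calls, 42.3% were rises with TMM scaling, 49.3% with DESeq2 size factors (5477 rises and 5622 falls), 19.0% with upper-quartile scaling (1685 and 7195) and 8.78% with library totals alone (759 and 7888). The median log2 fold change of all tested genes was -0.10, -0.03, -0.24 and -0.30 in the same order, and genes with a background share under 5% had a median of 0.24 with TMM scaling over all tested genes. Scaled on those 4729 genes alone, they had a median of -0.0017 with no background subtracted and of -0.0018 with it subtracted, and their fold changes correlated at 0.992 between these 2 fits. A value given after background subtraction is therefore relative to the other genes under that share, and its move from the main test comes mostly from this scaling and not from the subtraction. Lane 8 alone gave 67 rises and 153 falls (2 libraries against 2), a fit with 1 surrogate variable gave 105 and 44, and a fit with the background density as a covariate gave 4 and 16. Of the genes named here and below that were called in the main test, 87 of 99, 85 of 100 and 96 of 100 lost their calls in those 3 fits. In lane 8 the fold changes were of similar size (median 0.21 for genes with a share under 5%) and the libraries fewer, while with the surrogate variable and the covariate they shrank (medians 0.11 and 0.05).

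**Figure D2:**
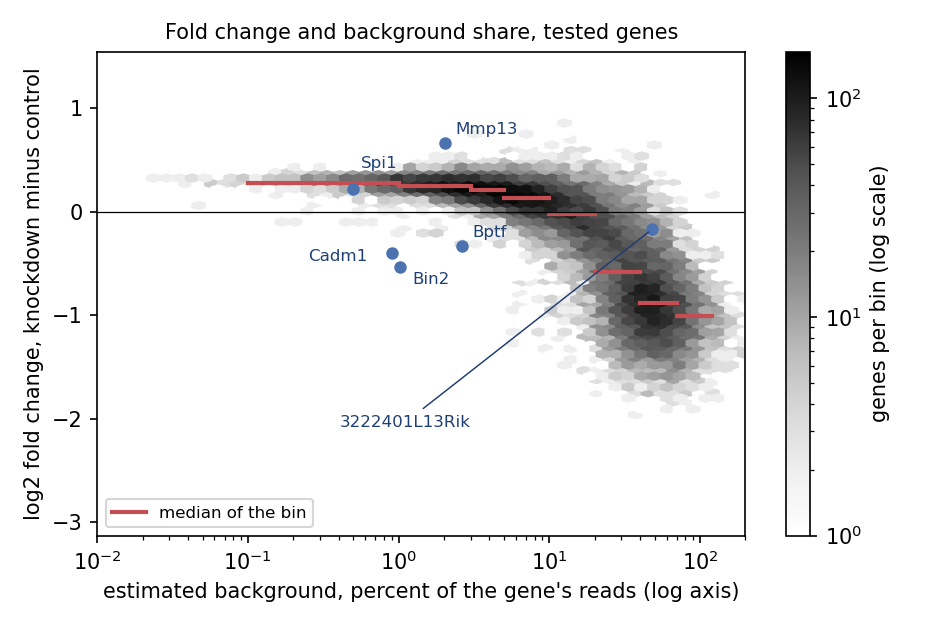
Log2 fold change (knockdown-labelled minus control, 5 libraries each) of tested genes against the percent of their reads predicted by the background density (log axis), with shading for the number of genes and red lines for the median of each background range. The median goes from 0.28 for genes under 1% to -1.01 for genes over 70%, with Mmp13 above that course and Cadm1, Bptf and Bin2 below it.

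Inflammatory genes did not move as 1 group. Of 29 tested cytokine and chemokine genes 9 rose, 5 fell and 15 were not called. The chemokine genes Ccl9 (log2 fold change 0.39, SE 0.06) and Ccl6 (0.31, SE 0.06) were among the rises. The falls were those of the interleukin-6 family cytokine gene Lif (-1.12), the chemokine genes Cxcl11 (-1.36) and Cxcl3 (-1.14), the interleukin-23 subunit gene Il23a (-1.11) and the inducible nitric oxide synthase gene Nos2 (-0.63), whose background shares were 29.9 to 76.8%. Adjusted over the list alone, 8 rose and 5 fell. The list median was 0.02 and its mean -0.14, while the camera test pointed up (adjusted p = 0.162, and adjusted p = 0.20 with an estimated correlation). Its median was -0.12 with upper-quartile scaling and -0.18 with library totals, where camera still pointed up (adjusted p = 0.0454), and with no filter on low counts it was 0.13 (adjusted p = 0.0027). The call of Il23a was lost without control replicate 2 (-0.82), and that of Nos2 without control replicate 2 (-0.52) or knockdown-labelled replicate 2 (-0.52). Of 22 NF-kB pathway genes 15 rose, among them the feedback inhibitor gene Tnfaip3 (0.36, SE 0.06) and the subunit gene Rela (0.31, SE 0.06), and 6 were not called. The adaptor gene Traf1 was the 1 that fell (-1.09, SE 0.23, background share 49.9%). Adjusted over the list alone the counts were again 15 and 1, with a median of 0.21 (camera adjusted p = 1.5e-04, and adjusted p = 0.198 with an estimated correlation), and with a stricter filter the median was 0.09 (camera adjusted p = 0.0676). Of 39 interferon response genes 26 rose, 0 fell and 13 were not called, with 28 rises adjusted over the list alone. Examples were the DNA sensor gene Ifi204 (0.37, SE 0.06), the transcription factor gene Irf7 (0.39, SE 0.07) and Oasl2 (0.32, SE 0.06), and the list median was 0.28 (camera adjusted p = 1.6e-08, and adjusted p = 0.203 with an estimated correlation). Rela and Irf7 lost their calls with library totals alone (0.10 and 0.19). Under a 5% share 11, 12 and 33 genes of these 3 lists were kept, the fallen genes named above not among them. The kept genes had medians of 0.30, 0.29 and 0.28 in the main test. Scaled on the genes under that share alone, they had medians of 0.05, 0.05 and 0.04 and camera adjusted p-values of 0.298, 0.639 and 0.258. With background reads also subtracted, the medians were 0.04, 0.06 and 0.04, 1 of their genes passed (Ccl9, 0.12, SE 0.03), and the camera adjusted p-values were 0.677, 0.677 and 0.45.

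Spi1, which encodes the myeloid transcription factor PU.1, and the genes it is known to control were higher by small amounts. Spi1 (ENSMUSG00000002111, chromosome 2, 91082390 to 91115756, plus strand) was at 206 ± 13.1 CPM in the control and 240.0 ± 15.8 CPM in the knockdown-labelled libraries (SD, n = 5 each), a log2 fold change of 0.22 (SE 0.06, 95% interval 0.10 to 0.34, edgeR quasi-likelihood test, adjusted p = 0.0016). Of 39 PU.1 target genes 36 rose, 1 fell and 2 were not called, or 37 and 1 adjusted over the list alone. They included the NADPH oxidase subunit gene Cybb (0.40, SE 0.06), the scavenger receptor gene Msr1 (0.39, SE 0.06), the Fc receptor subunit gene Fcer1g (0.36, SE 0.06) and Plek (0.36, SE 0.06). The Src family kinase gene Fgr was the 1 that fell (-0.83, background share 29.8%). The list median was 0.28 (camera adjusted p = 4.9e-15, and adjusted p = 0.198 with an estimated correlation). Its median background share was 0.584%, and 746 of all 853 tested genes under a 1% share rose, with the same median of 0.28. Scaled on the genes under a 5% share alone Spi1 was at -0.03 (SE 0.04, adjusted p = 0.797). With background reads also subtracted it was at -0.05 (SE 0.04, adjusted p = 0.610), so its move came with the scaling. With upper-quartile scaling of the original counts it was at 0.07 (adjusted p = 0.172), with library totals at 0.02, and with a stricter filter at 0.10 (adjusted p = 0.0783). With the scaling on genes under a 5% share alone the target list had a median of 0.04 and passed camera (adjusted p = 0.0120, or 0.566 with an estimated correlation, 6 of 36 tested genes called). With background reads also subtracted the median was 0.02, with 2 genes called (Cybb and Msr1, both 0.13, SE 0.03) and a camera adjusted p of 0.337. Cybb and Msr1 lost their calls with a GC correction (0.09 and 0.07), in lane 7 alone (0.11 and 0.14) and in lane 8 alone (0.15 and 0.11). With genes up to a 20% share kept, its median was 0.05 (camera adjusted p = 0.0016, and adjusted p = 0.365 with an estimated correlation).

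Most tested genes of the lists of microglial identity and of the phagocytic state rose. Of 25 homeostatic microglia genes 16 rose, among them Fcrls (0.45, SE 0.06), the growth factor receptor genes Csf1r (0.30, SE 0.06) and Tgfbr1 (0.32, SE 0.06), while 7 were not called. The lectin gene Siglech (-1.75, SE 0.32) and the adhesion receptor gene Adgrg1 (-0.59) fell, with background shares of 43.2 and 34.2%. The Adgrg1 call was lost without control replicate 2 (-0.44), without control replicate 3 (-0.53) or without knockdown-labelled replicate 2 (-0.47). The list median was 0.22 and its mean 0.06 (camera adjusted p = 1.4e-04, and adjusted p = 0.198 with an estimated correlation), with the same 16 and 2 calls adjusted over the list alone. Of 25 genes of damage-associated microglia 23 rose and 2 were not called, including the growth factor gene Igf1 (0.41, SE 0.06), the lipid carrier gene Apoe (0.35, SE 0.06) and the lysosomal protease genes Ctsb and Ctsl (both 0.36, SE 0.06). The list median was 0.29 (camera adjusted p = 1.6e-11, or 0.198 with an estimated correlation). Of 26 phagocytosis and complement genes 24 rose, such as the anaphylatoxin receptor gene C3ar1 (0.36, SE 0.06), and 2 were not called (median 0.28, camera adjusted p = 2.6e-11, or 0.198 with an estimated correlation). Of 31 lysosomal genes 28 rose and 3 were not called (median 0.28, camera adjusted p = 5.6e-14, or 0.198 with an estimated correlation). Of 29 actin and migration genes 27 rose and 2 were not called (median 0.28, camera adjusted p = 1.5e-12, or 0.198 with an estimated correlation, example Vim, 0.34, SE 0.06). In these last 4 lists 23, 24, 28 and 27 genes rose when adjusted over the list alone and 0 fell. Their median background shares were 0.255, 0.548, 0.467 and 0.791%. Of all 853 tested genes with a share under 1%, 746 rose, with a median of 0.28. Rises of this rate and size were thus not particular to these lists. Scaled on the genes under a 5% share alone, the kept members of these 5 lists (15 of 25 for homeostatic microglia) had medians of 0.03 to 0.06. The lysosome list and the actin and migration list passed camera there (adjusted p = 0.0084 for both), and lost their calls with an estimated correlation (adjusted p = 0.566 and 0.427). With background reads also subtracted the medians lay between 0.00 and 0.03 and the lowest camera adjusted p was 0.203. The mixed fry test, which counts changes in both directions, passed 9 of 22 lists there, among them phagocytosis and complement (adjusted p = 1.0e-06), lysosome (0.0010), homeostatic (0.0014) and damage-associated microglia (0.0041). The directional fry test passed none under a 5% share after subtraction (lowest adjusted p = 0.112). With that scaling and no subtraction it passed the actin and migration list (adjusted p = 0.0161). Under a 20% share, with background subtracted, it passed the actin and migration (0.0088), PU.1 target (0.0277) and lysosome (0.0495) lists. With genes up to a 20% share kept, the lysosome list and the actin and migration list passed again (median 0.06 and adjusted p = 0.0032 for both). They lost their calls with an estimated correlation (adjusted p = 0.484 and 0.330).

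The remaining lists of microglial programs had the same sign in the main test. Of 21 antigen presentation genes 9 rose, including Tapbp (0.33, SE 0.06), and 10 were not called, while the class II regulator gene Ciita (-0.85) and H2-Aa (-0.86) fell. The counts were equal when adjusted over the list alone (median 0.12, camera adjusted p = 0.0183, and adjusted p = 0.20 with an estimated correlation). Of 29 Toll-like receptor and inflammasome genes 13 rose, including Tlr7 (0.34, SE 0.06), 15 were not called and the interleukin-1 receptor gene Il1r1 fell (-0.66), again with 13 and 1 calls adjusted over the list alone (median 0.20, camera adjusted p = 3.0e-04, and adjusted p = 0.198 with an estimated correlation). Of 38 myeloid transcription factor genes 23 rose, including Irf5 (0.38, SE 0.06), and 11 were not called, while Fosb (-0.75), Runx3 (-0.89), Nr4a1 (-0.83) and Egr3 (-0.61) fell, with 23 and 4 calls adjusted over the list alone (median 0.23, camera adjusted p = 3.0e-06, and adjusted p = 0.198 with an estimated correlation). Of 18 anti-inflammatory and alternative activation genes 10 rose, including the interleukin-1 antagonist gene Il1rn (0.43, SE 0.06) and the mannose receptor gene Mrc1 (0.31, SE 0.06), and 6 were not called, while Socs1 (-1.07) and Cd163 (-0.85) fell, as many as when adjusted over the list alone (median 0.24, mean 0.02, camera adjusted p = 0.0029, and adjusted p = 0.198 with an estimated correlation). The fallen genes named here had background shares of 26.8 to 77.6%. The call of H2-Aa was lost in 5 of the fits that left out 1 library and that of Egr3 in 6 of them, and that of Cd163 without control replicate 2 (-0.56). With the scaling on genes under a 5% share none of these 4 lists passed camera, the lowest adjusted p being 0.324 without background subtraction and 0.677 with it, and after subtraction Il1rn (0.19, SE 0.05) was the 1 gene of them that was still called.

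Lists of growth, stress and metabolism behaved alike. Of 28 cell cycle genes 12 rose, including the proliferation genes Mki67 (0.27, SE 0.06) and Pcna (0.36, SE 0.08), and 16 were not called (median 0.17, camera adjusted p = 3.9e-04, or 0.20 with an estimated correlation, 12 rises adjusted over the list alone). Mki67 lost its call with library totals only (0.07). Of 23 p53 target genes 10 rose, including Plk2 (0.29, SE 0.06), 12 were not called and Tnfrsf10b (-0.54) fell (median 0.16, camera adjusted p = 0.0040, or 0.20 with an estimated correlation, 10 and 1 adjusted over the list alone). Of 22 genes of the unfolded protein and integrated stress response 14 rose, including the chaperone gene Hspa5 (0.37, SE 0.06), 7 were not called and Phgdh (-0.69) fell (median 0.21, camera adjusted p = 1.0e-04, or 0.198 with an estimated correlation, 14 and 1 adjusted over the list alone). Of 26 cholesterol and lipid genes 15 rose, including the lipid exporter gene Abca1 (0.35, SE 0.06), 10 were not called and 1 fell (median 0.19, camera adjusted p = 4.9e-04, or 0.198 with an estimated correlation, 15 and 1 adjusted over the list alone). Of 25 glycolysis and hypoxia genes 10 rose, including Pfkfb3 (0.32, SE 0.06), and 15 were not called (median 0.16, camera adjusted p = 0.0022, or 0.365 with an estimated correlation, 9 rises adjusted over the list alone). Of 33 oxidative phosphorylation genes 23 rose and 10 were not called (median 0.27, camera adjusted p = 1.6e-09, or 0.198 with an estimated correlation, 25 rises adjusted over the list alone). All 7 tested mitochondrially encoded genes rose, with mt-Co1 at 0.34 (SE 0.06) and a median of 0.28 (camera adjusted p = 3.2e-05, or 0.198 with an estimated correlation, 7 rises adjusted over the list alone). Of 69 ribosomal protein genes 19 rose, including Rpl22 (0.36, SE 0.06), and 50 were not called (median 0.16, camera adjusted p = 0.0010, or 0.20 with an estimated correlation, 16 rises adjusted over the list alone). The calls of Tnfrsf10b and Phgdh were lost in 8 and 7 of the 10 fits that left out 1 library. With the scaling on genes under a 5% share none of them passed camera, the medians being -0.07 to 0.03 and the lowest adjusted p 0.258 without background subtraction, and -0.09 to 0.03 and 0.203 with it.

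**Figure D3:**
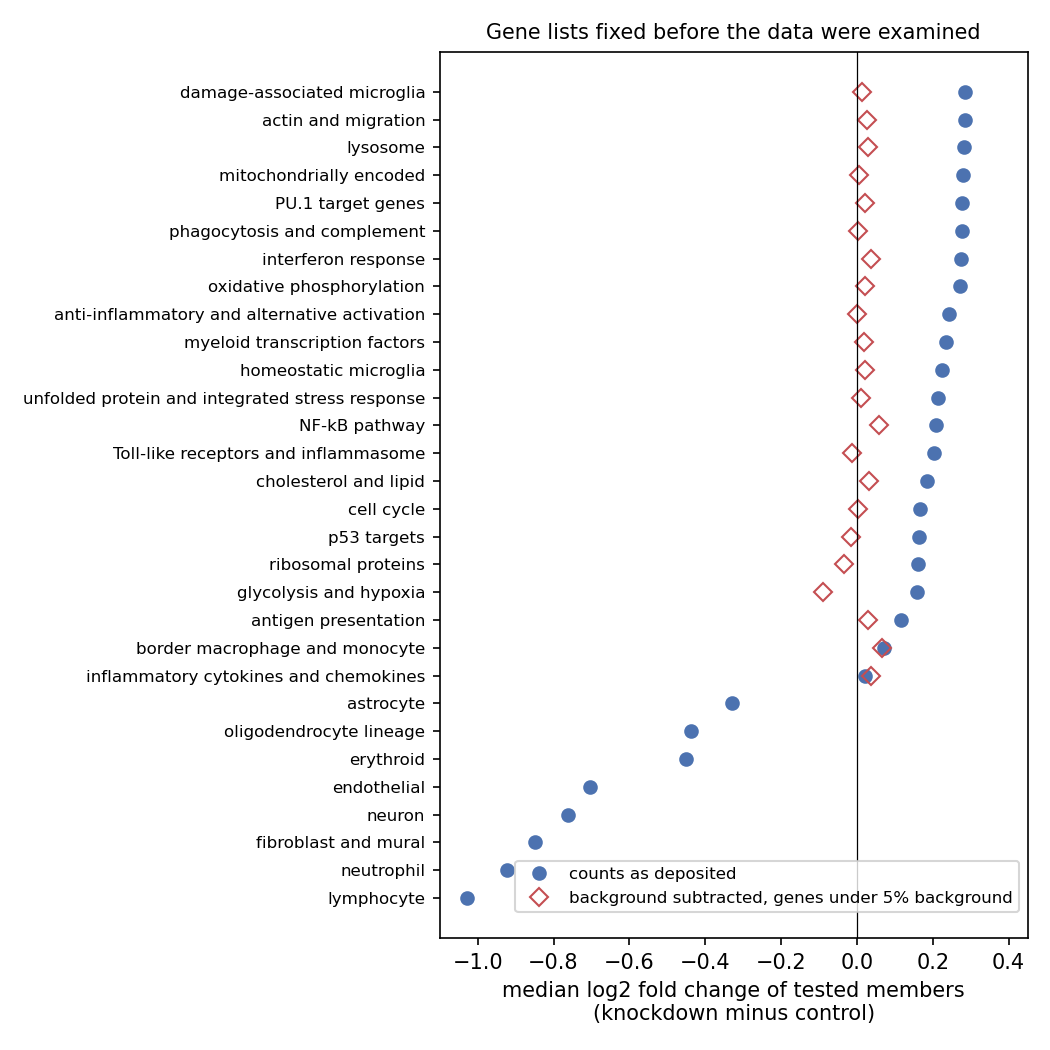
Median log2 fold change (knockdown-labelled minus control) of the tested members of each of 30 gene lists, from the counts as deposited (filled) and after background subtraction and scaling on genes under a 5% background share (open). Medians run from -1.03 for lymphocyte genes to 0.29 for damage-associated microglia genes as deposited, and from -0.09 to 0.06 after subtraction for the 22 lists tested there.

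Lists of marker genes of other cell types had negative medians in the libraries labelled knockdown, except for the border macrophage and monocyte list. All tested genes with a share of 20 to 40% had a median of -0.58, and those of 40 to 70% had -0.89. Negative medians at such shares are therefore not particular to these lists and do not show a difference in other cells. Of 12 neuron genes 10 fell, such as the GABA synthesis gene Gad1 (-1.19, SE 0.21) and the synaptic vesicle gene Syt1 (-1.32, SE 0.25), 0 rose and 2 were not called, with 10 falls adjusted over the list alone. The list had a median of -0.76 and a median background share of 47.6% (camera adjusted p = 8.9e-04, and adjusted p = 0.198 with an estimated correlation). Of 6 lymphocyte genes 5 fell, such as Ms4a1 (-1.29, SE 0.29), and 1 was not called, with 5 falls adjusted over the list alone and a median of -1.03 (share 50.7%, camera adjusted p = 0.0256, and adjusted p = 0.20 with an estimated correlation), a list call that was lost without knockdown-labelled replicate 5 (adjusted p = 0.0503) and in lane 7 alone (adjusted p = 0.0558). The endothelial list passed camera in 5 of the fits that left out 1 library, the fibroblast and mural list without control replicate 2 (adjusted p = 0.0464) and the neutrophil list without control replicate 3 (adjusted p = 0.0316). The other 7 marker lists did not pass camera. Fry called 28 of the 30 lists in the main test, and of these 7 it passed the astrocyte (adjusted p = 0.0106), oligodendrocyte lineage (0.0471), endothelial (0.0068), fibroblast and mural (0.0037) and neutrophil (0.0103) lists. Of 13 astrocyte genes 5 fell, 2 rose (Gfap, 0.32, SE 0.08, and Aqp4, 0.28, SE 0.09) and 6 were not called, or 7 and 2 adjusted over the list alone (median -0.33, share 29.9%, camera adjusted p = 0.338). Both Gfap and Aqp4 lost their calls with library totals only (0.11 and 0.07), and Aqp4 also with upper-quartile scaling (0.13). Of 11 oligodendrocyte lineage genes 3 fell, such as Pdgfra (-0.79) and Mobp (-0.88), Cnp rose and 7 were not called, or 2 and 1 adjusted over the list alone (median -0.44, share 46.3%, camera adjusted p = 0.552). Of 6 endothelial genes 5 fell, such as Pecam1 (-0.82), and Flt1 rose, as when adjusted over the list alone (median -0.70, share 26.9%, camera adjusted p = 0.115). Of 8 fibroblast and mural genes 7 fell, such as Pdgfrb (-0.91), and Postn rose, as when adjusted over the list alone (median -0.85, share 28.6%, camera adjusted p = 0.0506). Of 8 border macrophage and monocyte genes 2 rose, 3 fell and 3 were not called, as when adjusted over the list alone (median 0.07, mean -0.16, share 28.7%, camera up, adjusted p = 0.841). Of 5 neutrophil genes 3 fell, such as the myeloperoxidase gene Mpo (-0.98), and 2 were not called, while 5 fell adjusted over the list alone (median -0.92, share 29.2%, camera adjusted p = 0.0789). The 2 tested erythroid genes were not called, over all genes or over the list alone (median -0.45, share 35.6%, camera adjusted p = 0.558). With an estimated correlation the adjusted p-values of these 7 lists were 0.264 to 0.841. Under a 5% share the neuron, lymphocyte, fibroblast and mural, neutrophil and erythroid lists held 0 tested genes. The astrocyte, oligodendrocyte lineage and endothelial lists held 1 each, so these lists could not be tested again there.

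Because the background density moved with the label, the comparison was also run on counts with the expected background reads subtracted, over genes with a background share under 5%, a choice made after the data were seen. There the adhesion molecule gene Cadm1 had the smallest p-value. It was at 548 ± 42.3 CPM in the control and 415 ± 23.9 CPM in the knockdown-labelled libraries before subtraction (SD, n = 5 each), a log2 fold change of -0.40 (SE 0.06), and its log2 fold change after subtraction was -0.67 (SE 0.03, edgeR quasi-likelihood test, adjusted p = 1.1e-23). Bptf, a subunit of the chromatin remodelling complex NURF, fell from 245 ± 11.5 to 195 ± 4.14 CPM (-0.33 before and -0.59 after subtraction, SE 0.04, adjusted p = 4.3e-20). Bin2, which encodes a membrane-bending BAR protein of blood cells, fell from 121 ± 13.6 to 83.6 ± 5.06 CPM (-0.54 before and -0.81 after subtraction, SE 0.05, adjusted p = 8.4e-20). With the same scaling and no subtraction these 3 genes were at -0.64, -0.58 and -0.78. In each of them all 5 knockdown-labelled libraries lay below all 5 control libraries. AC149090.1, on a scaffold outside the placed chromosomes, fell by 0.63 (SE 0.06, adjusted p = 1.4e-11), Rnf121 by 0.51 (SE 0.08, adjusted p = 5.8e-05) and Stard8 by 0.34 (SE 0.05, adjusted p = 7.2e-07). Stard8 was at -0.09 in the main test (adjusted p = 0.237) and at -0.33 with the scaling alone. Mmp13 rose by 0.43 (SE 0.07, adjusted p = 4.4e-05), the fatty acid binding protein gene Fabp4 by 0.26 (SE 0.05, adjusted p = 1.5e-04), the diacylglycerol kinase gene Dgkd by 0.25 (SE 0.04, adjusted p = 1.8e-05), the nucleic acid binding protein gene Cnbp by 0.19 (SE 0.04), Fcrls by 0.18 (SE 0.03, adjusted p = 5.5e-04) and Igf1 by 0.13 (SE 0.02, adjusted p = 2.3e-04).

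In all, 34 genes rose and 48 fell of 4729 tested after subtraction, with 696 at an unadjusted p under 0.05. The risen genes had a median log2 fold change of 0.14 and all 34 had also risen in the original counts. The fallen genes had a median of -0.24, and 16 of the 48 had also fallen in the original counts. In the main test 3570 of the 4728 genes under this share were called higher, with a median of 0.24 for all 4728. These overlaps thus follow largely from the scaling and are no separate support. Falls of more than 2-fold numbered 11, the largest at -1.91 in the rRNA gene n-R5s207 (SE 0.40, 3.54 CPM in the control libraries). They included Gm10717 (-1.56) and Gm10720 (-1.41), which belong to the pericentromeric repeat genes that were higher in the control libraries. With the same genes and scaling and no subtraction 103 rose and 89 fell. Some background may remain in the calls made after subtraction. Subtraction used the olfactory density (0.599 in the control libraries), while keratins were at 1.31 and vomeronasal receptors at 0.385. Of the fallen genes Utrn and Lama3 had shares of 4.83 and 4.46%, near the limit, and Dock2 0.59%. Of the risen genes Ctsb and Cybb had 0.02 and 0.20%, and Reps2 3.19%. The small changes are therefore not shown to be free of background. With genes up to a 20% background share kept, 231 rose and 321 fell of 10112 tested. Cadm1 lies on chromosome 9 at 47530173 to 47857637 (plus strand), Bptf on chromosome 11 at 107033081 to 107132127 (minus strand), Bin2 on chromosome 15 at 100641077 to 100669553 (minus strand) and Mmp13 on chromosome 9 at 7272514 to 7283331 (plus strand), all in GRCm38. These 4 genes kept their call in each of 24 alternative fits after subtraction, and also in lane 8 alone, which that range leaves out, with log2 fold changes of -0.71 to -0.64 for Cadm1, -0.62 to -0.56 for Bptf, -0.92 to -0.76 for Bin2 and 0.38 to 0.47 for Mmp13. In lane 8 alone the 4 genes were at -0.61, -0.54, -0.64 and 0.50. In lane 8 alone, where 2 genes rose and 4 fell, Mmp13 and Fabp4 were the rises. There Igf1 (0.14), Fcrls (0.11), Dgkd (0.21), Stard8 (-0.29) and Rnf121 (-0.45) lost their calls. Against a 1.2-fold change (glmTreat) Cadm1, Bptf and Bin2 kept their calls after subtraction and Mmp13 did not (adjusted p = 0.633). The count of falls was 30 without control replicate 2, 30 without knockdown-labelled replicate 5 and 30 with the background density multiplied by 1.5.

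**Figure D4:**
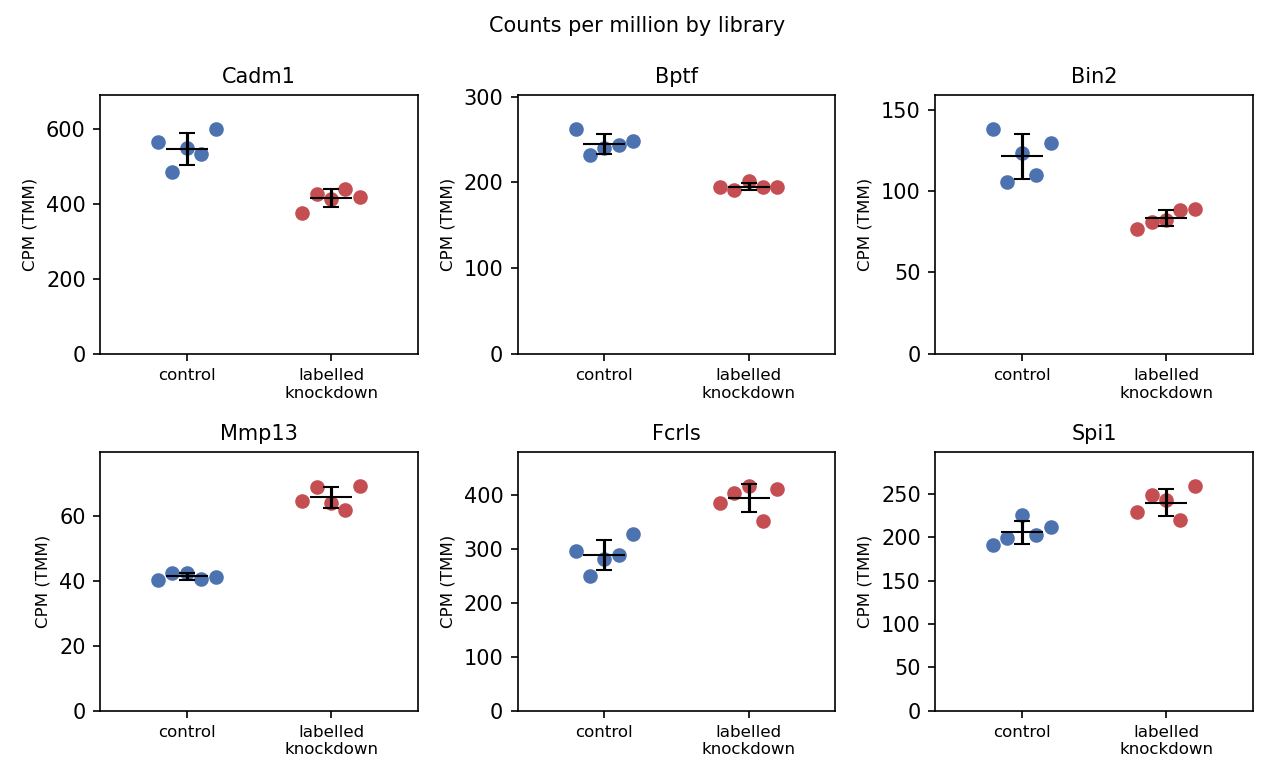
Counts per 1000000 reads (TMM-scaled, counts as deposited) of 6 genes in each of 5 control and 5 knockdown-labelled libraries, with lines for the mean and bars for the SD. Cadm1, Bptf and Bin2 were lower in all 5 knockdown-labelled libraries than in any control library, and Mmp13 was higher.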

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

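The thinning of counts, the fit with library totals and the splits of the libraries were chosen before the results were seen, and the tests with background density, GC content, shared sequence and subtracted counts only after.

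In 8 of 230 groups of 5 libraries examined, 1 library lay far from the other 4 by its gap over the range, where chance gives about 1 in 20. Slc13a3 was at 88.4 CPM in control replicate 5 and at most 64.4 CPM in the other control libraries. Spink10 was at 3.93 CPM in control replicate 5 and at least 7.93 CPM in the others. Cxcl11 was at 1.96 CPM in control replicate 5 and at least 3.10 CPM in the others. Traf1 was at 7.96 CPM in knockdown replicate 4 and at most 4.73 CPM in the others. Mobp was at 7.79 CPM in knockdown replicate 4 and at most 3.78 CPM in the others. Mki67 was at 374.1 CPM in knockdown replicate 1 and at least 412.2 CPM in the others. Arap3 was at 189.4 CPM in knockdown replicate 1 and at least 205.4 CPM in the others. Cd163 was at 5.86 CPM in knockdown replicate 1 and at most 3.89 CPM in the others.

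Of 19263 genes, 4418 rose and 6033 fell, and their direction followed the share of reads that an even background over exons predicts. In a model with group and background density, 94.36% of the lower genes went up with density and 93.91% of the higher genes went down with it. A background larger in the control libraries predicts these directions, so it is a candidate explanation for the direction of most of both sets. The sizes were not tested. Simulated with the measured density, 2109 unchanged genes were called higher and 3134 lower, fewer than here. That simulation treated any background above the olfactory density as signal equal in both groups, so it could only call too few. The 12 named falls, picked for size, were -1.43 to -1.78. Genes with a share over 70% had a median of -1.01 and a 10th percentile of -1.46. The measured density was thus not shown to account for all calls or their size, and neither comparison shows that background falls short. Deeper sequencing and the scaling factor are argued against as the cause of the falls, since 4667 genes were lower with thinned counts and 7888 with library totals only. This does not hold for the scaling factor and the rises. Higher genes numbered 3639 with thinned counts but 759 with library totals only, so the scaling factor stays a candidate explanation for most rises. A chance split of these libraries is argued against, as 1 of 100 splits, the real one, gave as many lower genes (6033, highest other 2887 in either direction). Likewise 1 of 100 gave as many higher genes (4418, highest other 2887 in either direction, of lower genes). That is the smallest share these splits can give. The split that called 2887 also parted the libraries by background, with a density difference of 0.298 against 0.342. Splits cannot tell the label from a technical difference that moved with it. The gapmer as a cause of the difference in background was not tested and stays open.

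Cadm1, Bptf and Bin2 had the smallest adjusted p-values after background subtraction, with log2 fold changes of -0.67, -0.59 and -0.81. With background density as a covariate the smallest of the 3 falls was -0.432 (Bptf), and with a GC correction it was -0.5788 (Bptf), each with its call. The second value argues against GC content as the whole cause. An even background predicted only 0.90, 2.65 and 1.02% of the reads of Cadm1, Bptf and Bin2, which argues against it as the whole cause. The covariate fit adds little to this, since those shares were too small for another outcome. Group and density also correlated at -0.858 in it. For AC149090.1 the fall went from -0.63 (SE 0.06) to -0.2427 (SE 0.10) with the covariate and lost its call, because the error grew and the fall shrank. An even background predicted 2.13% of its reads, and with the scaling alone it was at -0.61. These values argue against an even background of the measured density as the cause of its fall. Any other difference that moved with the density cannot be told apart from the gapmer for that gene. Sequence shared with 3222401L13Rik that a gapmer could bind stays open: 1 of the 3 genes (Bptf, 18 bases) held a shared run of 16 or more bases, Cadm1 had 13 and Bin2 11, runs as long were found in 13.04%, 70.6% and 98.6% of genes of like length, and introns and the gapmer sequences were not searched. A response to the gapmer, through 3222401L13Rik or not, is a hypothesis that these data leave open. For the set, 1 of 100 splits, the real one, gave as many lower genes (48, highest other 30 in either direction). Likewise 1 of 100 gave as many higher genes (34, highest other 30 in either direction, of lower genes). This argues against a chance split, more weakly for the higher genes, and cannot tell the label from a technical difference that moved with it.

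3222401L13Rik was not lower in the libraries labelled knockdown. More background was predicted for the control libraries (18.9 reads against 9.88), so subtraction could only raise its fold change. The value after subtraction, 0.4109 in log2, is therefore no test of whether background reads hid a fall. Its 95% interval was -0.35 to 1.17. That interval rests on about 11.9 and 19.3 reads per library and still allows a fall to 0.785 times the control level. Exchanged or wrong labels, a fall seen only in one part of the transcript, and reads of the overlapping genes were not tested and stay open.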

How the results depend on the processing

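The fits with background subtraction, with the background density as a covariate and with a GC correction were chosen after the data were seen, and the other alternatives before the data were examined. The fits with background subtracted were also scaled on the kept genes alone. 3222401L13Rik passed no test under any alternative, and the sign of its change in the counts as deposited was the same in all of them. The counts of 4418 higher and 6033 lower genes stayed within 1.5 times with DESeq2 size factors, the DESeq2 Wald test, limma-voom, lane 7 alone and thinned counts. Higher and lower genes numbered 1685 and 7195 with upper-quartile scaling, 759 and 7888 with library totals only, 2057 and 2239 with a stricter filter, which tests fewer genes, 67 and 153 in lane 8 only, which has fewer samples, 105 and 44 with 1 surrogate variable, 4 and 16 with the background density covariate, 34 and 48 with background subtracted under 5%, 231 and 321 under 20%, and 18 and 42 with a GC correction added. Against a 1.2-fold change (glmTreat) 202 genes were higher and 4397 lower. Leaving out 1 library gave 4032 to 5015 higher and 4928 to 6967 lower genes. After background subtraction, higher and lower genes numbered 128 and 121 with the density of vomeronasal receptors, 26 and 30 with the density multiplied by 1.5, 103 and 89 with the same genes and no subtraction, 10 and 18 in lane 7 only, 2 and 4 in lane 8 only, 44 and 77 with 1 surrogate variable, 18 and 24 at an adjusted p under 0.01, and 0 and 10 by edgeR glmTreat, where 696 genes had an unadjusted p under 0.05 in the quasi-likelihood test. Leaving out 1 library gave 24 to 49 higher and 30 to 45 lower genes, with 30 lower without control replicate 2 or knockdown replicate 5. With the replicate block 4405 genes were higher and 5949 lower, and after subtraction 57 and 70. Libraries sharing a number correlated at -0.21 to 0.16 in their deviations from group means, those of other numbers at -0.34 to 0.37, and 2 of 10 correlated best with their own number. After subtraction these were -0.18 to 0.40, -0.39 to 0.28 and 3 of 10, so pairs are not shown and not excluded there. The block ended the calls of Tnfrsf10b and Egr3. Spi1 was at 0.075 with upper-quartile scaling, 0.015 with library totals only, 0.10 with the stricter filter, 0.23 in lane 8 only, 0.10 with the surrogate variable and 0.10 with the covariate, all without a call. With background subtracted it was -0.050 under 5%, -0.021 under 20% and -0.018 with the GC correction. Without 1 library Spi1 ranged from 0.21 to 0.27, 3222401L13Rik from -0.25 to -0.08, and list medians from 0.22 to 0.28 (homeostatic microglia), -0.025 to 0.12 (cytokines), 0.19 to 0.25 (NF-kB), 0.25 to 0.34 (interferon response) and 0.24 to 0.34 (PU.1 targets). Camera calls were lost with an estimated correlation at unmoved medians of homeostatic microglia 0.22, NF-kB 0.21, interferon response 0.28 and PU.1 targets 0.28. They were also lost after subtraction under 5%, where medians were homeostatic microglia 0.022, NF-kB 0.059, interferon response 0.038 and PU.1 targets 0.023, with the GC correction (homeostatic microglia 0.028, NF-kB 0.081, interferon response 0.029 and PU.1 targets 0.033) and under 20% (homeostatic microglia 0.024, NF-kB 0.044 and interferon response 0.066), and for NF-kB with the stricter filter (0.089). The cytokine list gained a call with library totals only (-0.18), with no filter (0.13) and by fry (0.023). Some medians fell below 0 while the direction of the list test stayed up. They included the anti-inflammatory list under 5% (-0.00043), ribosomal proteins under 20% (-0.00090) and cytokines with upper-quartile scaling (-0.12) and library totals only (-0.18). The direction of the list test turned as follows, with list medians. Under 5% the turned lists were Toll-like receptors -0.014, p53 targets -0.016, glycolysis and hypoxia -0.089 and ribosomal proteins -0.035. With the GC correction they were Toll-like receptors -0.026, cell cycle -0.00019, p53 targets -0.033, glycolysis and hypoxia -0.070, mitochondrially encoded -0.056 and ribosomal proteins -0.022. Under 20% they were p53 targets -0.0077, glycolysis and hypoxia -0.058 and oligodendrocyte lineage 0.038. With the covariate, where glycolysis and hypoxia passed camera downwards (adjusted p = 0.0485), they were glycolysis and hypoxia -0.10, oligodendrocyte lineage -0.029, endothelial -0.0034, neutrophil 0.031, erythroid 0.30 and ribosomal proteins -0.015. With the surrogate variable they were glycolysis and hypoxia -0.040, oligodendrocyte lineage 0.0076 and erythroid 0.15. The test of the border macrophage list turned with no filter (-0.60), the stricter filter (-0.40), lane 7 only (-0.043) and fry (0.071). Genes turned in direction with upper-quartile scaling (Dock2 -0.0015, Elmo1 -0.090, Fcgr2b -0.032 and Cacna1a -0.074), library totals only (Dock2 -0.061, Elmo1 -0.15, Fcgr2b -0.091, Cacna1a -0.13 and Arap3 -0.051), the stricter filter (Elmo1 -0.062, Fcgr2b -0.0041 and Cacna1a -0.047), no filter (0.041 for Stard8) and lane 8 only (0.094 for Egr3). With the surrogate variable they were Traf1 0.0012, Gfap -0.0039, Elmo1 -0.12, Fcgr2b -0.089, Pdgfra 0.18, Phgdh 0.30 and Egr3 0.0088. Under 5% they were Dock2 -0.13, Elmo1 -0.17, Fcgr2b -0.15, Cacna1a -0.19, Diaph1 -0.029 and Arap3 -0.10, with the GC correction Dock2 -0.12, Elmo1 -0.18, Fcgr2b -0.16, Cacna1a -0.16, Diaph1 -0.012 and Arap3 -0.073 and under 20% Dock2 -0.10, Elmo1 -0.15, Fcgr2b -0.12, Cacna1a -0.16 and Arap3 -0.072. With the covariate they were Traf1 0.26, Ms4a1 0.039, Mki67 -0.028, Pcna -0.052, Elmo1 -0.17, Fcgr2b -0.13, Adgrg1 0.13, Nos2 0.0083, Cacna1a -0.047, Pdgfra 0.19, Arap3 -0.10, Tnfrsf10b 0.15, Phgdh 0.24, Cd163 0.27 and Egr3 0.34. Of the named genes, 999 of 1040 values kept their direction and side of the threshold without 1 library, 38 lost a call and 3 gained one. For lists without 1 library, 242 of 250 did so, 1 lost a call and 7 gained one. Lanes and groups showed no interaction past the threshold (0 genes by edgeR, 878 at an unadjusted p under 0.05, and 0 and 193 after subtraction). The cause was not tested where none is named here. At this depth and with no background difference the simulated test found 30% of genes changed 1.2-fold and 92% of those changed 1.5-fold. The runs with that difference had a lower noise setting and changed only genes under a 5% background share, so their yields cannot be compared with these. They found 54% of genes changed 1.2-fold, with 5243 unchanged genes also called, and 75.6% of the 45 tested after subtraction.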

Other observations

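The counts after background subtraction, and the genes named here from them, were chosen after the data were seen.

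After background subtraction the higher genes included 4 genes of the damage-associated microglia list, by small amounts. Apoe rose by 0.07 (SE 0.02, edgeR quasi-likelihood test, adjusted p = 0.0423), Ctsb by 0.08 (SE 0.02, adjusted p = 0.0028) and Ctsl by 0.09 (SE 0.02, adjusted p = 0.0465), beside Igf1 (0.13), with 5 libraries per group. Of the 25 tested genes of that list 14 had positive log2 fold changes, 5 were higher and 3 lower when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.677). Igf1 lost its call with the GC correction (0.07) and in lane 8 alone (0.14), and Fabp4, which is outside the list, in lane 7 alone (0.22). The phagocytosis and complement list held 1 higher gene (Msr1) and 3 lower genes. Dock2, an activator of the GTPase Rac, fell by 0.13 (SE 0.03, adjusted p = 0.0047), its partner Elmo1 fell by 0.17 (SE 0.05, adjusted p = 0.0351) and the inhibitory Fc receptor gene Fcgr2b fell by 0.15 (SE 0.04, adjusted p = 0.0353). With genes up to a 20% share kept, Fcgr2b lost its call (-0.12, edgeR adjusted p = 0.0655), while Dock2 and Elmo1 kept theirs (adjusted p = 0.0294 and 0.0498). In the main test Dock2 was higher (0.14, adjusted p = 0.0268), and Elmo1 and Fcgr2b had positive log2 fold changes without a call. With the scaling on genes under a 5% background share and no subtraction the 3 genes were lower too (-0.10, -0.19 and -0.13), so their direction depends on the scaling.

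The fit with background density as a covariate called 4 higher genes, Mmp13, Tor3a, Ranbp2 and Gbp3, and 16 lower genes, with 1430 genes at an unadjusted p under 0.05. Group and density correlated at -0.858 across the 10 libraries, so that fit had little left to separate them. Of the 99 other splits drawn, 94 called no gene after subtraction by the edgeR test.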
